A study of Mus musculus with 10 samples.

How the data were processed

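RNA was sequenced from the livers of 10 mice, 5 labelled NIKflox and 5 labelled NIKhKO. All were kept on the Lieber-DeCarli liquid diet with 5% ethanol for 4 weeks, per the labels. NIK (NF-kB inducing kinase) is encoded by Map3k14. The labels do not spell out hKO, and the series title speaks of hepatic NIK. Which part of the gene the allele removes is not given in the sources used here. No label says that the libraries of a genotype come from separate litters or cages, so p-values measure only the spread between these samples.

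One deposited table held 55401 genes with an FPKM value and a whole-number estimated count for each library. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR without a version, and give no role or order for them. Those notes name hg38, a human build, although the gene identifiers are mouse Ensembl identifiers. Of these, 55141 were found in the mouse GENCODE M21 annotation of GRCm38, and 51957 genes (93.8%) had the same start and end there. Coordinates are therefore given as the table gives them, and read as GRCm38. The FPKM values, fragments scaled to transcript length and library size, were computed by the authors, per the file headers. Genes with a count of 0 are listed in the table at an FPKM of 1e-04. The deposited estimated counts are not normalized. They follow FPKM times transcript length, and their low values pile up at multiples of 4. A library held on average 907 genes at a count of 4, against 330.5 at 3 and 175.8 at 5. One count is thus worth less than one read pair, so that the totals overstate depth and any interval from them covers counting error only.

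The design fixed before the data were examined had assumed a table of FPKM alone and limma, with edgeR if counts were present. Since the table held estimated counts, edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, TMM normalization, two-sided, Benjamini-Hochberg adjustment) on the counts, which are whole numbers already, was the test of single genes, and limma 3.58.1 on log2(FPKM + 1) became an alternative. Genes with a mean FPKM of at least 0.5 over the 10 libraries were tested, 12731 in all. Map3k14 (mean FPKM 0.494) was kept whatever its level. Log2 fold changes are NIKhKO minus NIKflox, standard errors are the log2 fold change divided by the square root of the F statistic, and a gene was called at an adjusted p below 0.05. Library shares and the 3 genes of the study title were also compared with exact two-sided permutation tests over all 252 arrangements, of which the smallest possible p is 0.0079, adjusted over the 7 quantities tested that way.

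Before the data were examined, 40 gene lists were fixed, for pathways, liver zonation, sex-biased liver genes and cell types. The 38 lists with at least 5 tested members, and 3045 GO and KEGG terms that the table itself pairs with 10 to 300 tested genes, were tested with limma's camera on log2(FPKM + 1) with a preset correlation between genes of 0.01. Camera with an estimated correlation, and fry, were run beside it. Neutrophil markers and pancreas and gut markers had 3 tested members each and were not tested. Members of each list were also adjusted over the list alone. Named genes followed a fixed rule. Map3k14, Inpp5b and Acly were always named. Next came the 10 called genes with the largest change in each direction, with a mean FPKM of at least 1, a regular symbol and ranges that do not overlap between genotypes, filled up by the smallest unadjusted p where fewer than 10 were called. In each list described, the members that passed over all genes were named, and otherwise the 3 with the smallest p. Genes named outside this rule were chosen after their values were seen, and 2 genes that the rule names are not reported here.

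The gene test was tested on simulated counts drawn for the 12731 genes with 50 genes changed at each fold size. It recovered 14% of the genes changed 1.5-fold, 82% of those changed 2-fold, 94% of those changed 4-fold and 92% of those changed 8-fold, with 7 false calls among 12531 unchanged genes. The simulated counts were independent between genes and held no outlying library. They also held many more changed genes than the 3 called in the real data, which eases the adjustment. These shares are therefore not the power in the real libraries, where Cyp2b13 (2.24-fold) and Egfr (2.53-fold) did not pass. Alternatives covered the pseudocount, the filter, 3 scalings of the FPKM values, sample weights, robust shrinkage, the replicate number as a block, DESeq2 1.42.0 and leaving out each library. RLE size factors, estimated counts divided by 4, voom with sample weights, edgeR's filterByExpr, camera on log2 CPM and leaving out pairs of libraries were added after seeing the data. The design's own test, limma on log2(FPKM + 1), was run as an alternative once the table proved to hold counts. Total counts ran from 47161869 to 65052525 per library, and correlations between libraries of log2 expression from 0.942 to 0.972. No 2 libraries held identical values.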

Results

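Liver RNA was profiled in 5 NIKflox and 5 NIKhKO mice that had received the ethanol liquid diet, to ask what loss of hepatic NIK changes in the ethanol-fed liver. The study title links NIK to INPP5B, an inositol polyphosphate 5-phosphatase, and to lipogenesis through PI3K, AKT and ACLY, the ATP citrate lyase that makes cytosolic acetyl-CoA. Total estimated counts ran from 47161869 in NIKflox 1 to 65052525 in NIKflox 4, with the NIKhKO libraries between 53225028 and 64321202. Mitochondrial transcripts took 9.38 ± 1.53% and 10.8 ± 1.96% of counts (exact permutation p = 0.25, adjusted p = 0.34). Ribosomal and small non-coding RNA took 0.519 ± 0.301% of counts in NIKflox and 1.17 ± 0.771% in NIKhKO (SD, n = 5 each; exact permutation p = 0.12, adjusted p = 0.28), with NIKhKO 3, 4 and 5 at 1.64, 1.37 and 2.08%. All 10 libraries expressed Xist, at 14.4 to 20.8 FPKM.

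Map3k14, which encodes NIK, was lower in NIKhKO livers. Its level was 0.606 ± 0.168 FPKM (SD, n = 5) in NIKflox and 0.383 ± 0.0372 FPKM (SD, n = 5) in NIKhKO, or 63.1% of the NIKflox mean. The 5 NIKflox libraries read 0.553, 0.51, 0.585, 0.899 and 0.483 FPKM, and the 5 NIKhKO libraries 0.347, 0.361, 0.443, 0.389 and 0.373 FPKM, so the ranges did not overlap. The exact permutation test of the means gave p = 0.0079, the smallest possible, and 0.056 after adjustment over 7 quantities. In edgeR's quasi-likelihood test the log2 fold change was −0.59 (SE 0.19), with an unadjusted p of 0.0098 and an adjusted p of 0.33 over all genes, so that Map3k14 (ENSMUSG00000020941, chromosome 11, 103219762 to 103267472, minus strand) was not called. Its counts were 145 to 427 per library, at the low end of the genes tested.

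Neither of the other genes of the study title passed a test of RNA level after adjustment. Inpp5b (ENSMUSG00000028894, chromosome 4, 124741850 to 124801511) read 8.01 ± 0.472 FPKM in NIKflox and 7.31 ± 0.134 FPKM in NIKhKO (SD, n = 5 each; exact permutation p = 0.040, adjusted p = 0.14). Its edgeR log2 fold change was −0.07 (SE 0.08, adjusted p = 0.83). Acly (ENSMUSG00000020917, chromosome 11, 100476353 to 100528000) read 47.5 ± 10 FPKM and 53.2 ± 15.0 FPKM (SD, n = 5 each; exact permutation p = 0.58, adjusted p = 0.66), with an edgeR log2 fold change of 0.24 (SE 0.20, adjusted p = 0.77). An approximate 95% interval of the Acly log2 fold change, from its SE and the normal distribution, ran from −0.16 to 0.63. With 5 libraries per genotype this interval is somewhat too narrow. NIKhKO 3, at 79.6 FPKM, stood above the other NIKhKO libraries, and without it the Acly log2 fold change was 0.02.

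**Figure D1:**
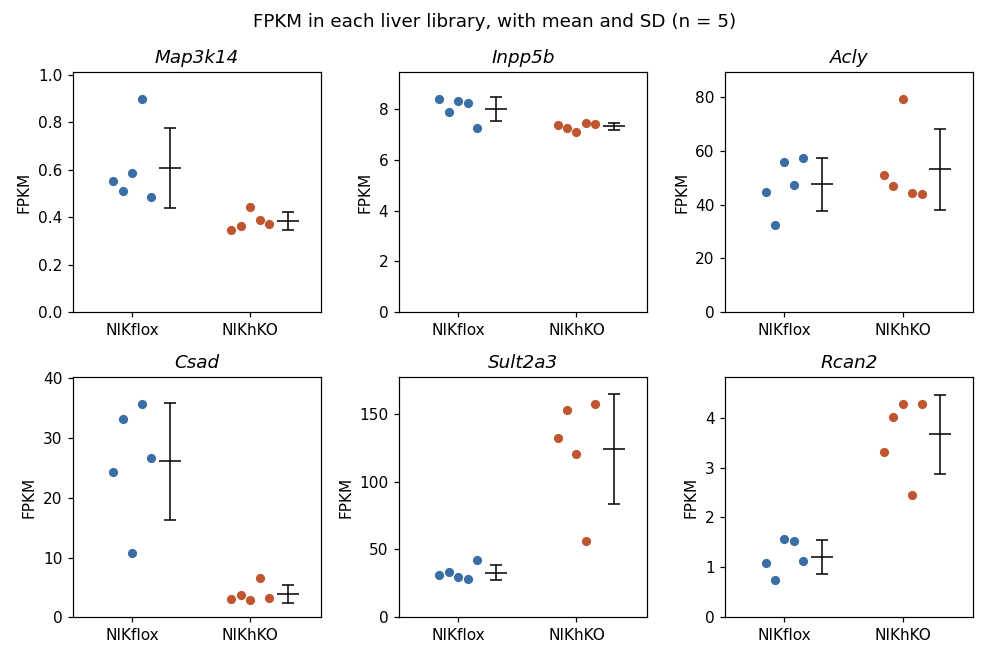
FPKM (vertical axes, linear from 0) of Map3k14, Inpp5b, Acly and the 3 called genes in each library of NIKflox and NIKhKO livers; points are libraries, and the bar beside them is the mean with its SD (n = 5). The genotypes do not overlap for Map3k14, Csad, Sult2a3 and Rcan2, and overlap for Inpp5b and Acly.

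Of 12731 genes tested, 3 differed between the genotypes at an adjusted p below 0.05 in edgeR's quasi-likelihood test, 2 higher and 1 lower in NIKhKO, each at an adjusted p of 0.031. Csad, the cysteine sulfinic acid decarboxylase of taurine synthesis, fell from 26.1 ± 9.79 to 3.91 ± 1.53 FPKM (SD, n = 5 each), a log2 fold change of −2.67 (SE 0.33). Sult2a3, a sulfotransferase of the family that acts on steroids and bile acids, rose from 33.0 ± 5.65 to 124 ± 40.6 FPKM, a log2 fold change of 1.97 (SE 0.25). Rcan2, a regulator of calcineurin, rose from 1.22 ± 0.342 to 3.66 ± 0.785 FPKM, a log2 fold change of 1.66 (SE 0.21). Each of the 3 changed in the same direction in 5 of 5 NIKhKO livers against all NIKflox livers. NIKhKO 4 lay nearest to NIKflox for all 3 genes, with 6.57 FPKM of Csad, 56.4 FPKM of Sult2a3 and 2.44 FPKM of Rcan2. Csad (ENSMUSG00000023044) lies on chromosome 15 at 102176999 to 102204253, Sult2a3 (ENSMUSG00000074375) on chromosome 7 at 14067446 to 14123044, and Rcan2 (ENSMUSG00000039601) on chromosome 17 at 43801351 to 44039060. Sult2a3 belongs to a cluster of near-identical genes, between which the authors' counting could split reads, so its level is uncertain.

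The 3 calls depended on single libraries. No gene passed without any 1 of NIKflox 1, 2, 4 or 5, or of NIKhKO 1, 2, 3 or 5; without NIKflox 3 the called genes were Csad, Rcan2 and Orm3, and Sult2a3 was lost. Without NIKhKO 4 there were 16 higher and 8 lower, with all 3 genes among them. limma on log2(FPKM + 1) called 0 genes, with 1375 at an unadjusted p below 0.05, and DESeq2 called 126 higher and 81 lower. The DESeq2 calls with the smallest p-values included the heart muscle genes Actc1 and Myl2. Actc1 read 2.90 and 10.4 FPKM in NIKflox 2 and 4 and was at the floor in the other libraries, so the DESeq2 count is not one of genotype alone. In edgeR 1273 genes had an unadjusted p below 0.05, against 637 expected on average by chance. Other splits of the 10 libraries into 5 and 5 gave a median of 511 and up to 1835. The ranges of the genotypes did not overlap for 280 genes (2.20%), against 0.79% on average by chance. This number was not compared with other splits.

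Other genes with ranges that did not overlap had the next smallest p-values and did not pass. On the higher side in NIKhKO these included Cyp2b13 (163 ± 34.1 against 351 ± 60.2 FPKM, NIKflox first), a female-biased liver cytochrome P450, Ociad2 (6.35 ± 0.977 against 11.4 ± 1.84 FPKM), Adhfe1 (18.3 ± 2.18 against 26.6 ± 2.10 FPKM), Serpinb1a, Pphln1, Klk1b4 and Slc22a29. Adhfe1 is named after the iron-containing alcohol dehydrogenase family, and the name does not show that it acts on ethanol. Their log2 fold changes ran from 0.61 for Adhfe1 to 1.93 for Slc22a29, with edgeR adjusted p-values from 0.056 for Cyp2b13 to 0.10 for Slc22a29. On the lower side these were Serpina11 (49.8 ± 6.59 against 22.1 ± 6.07 FPKM, adjusted p = 0.056), Dynll1, the glucuronosyltransferase Ugt2b5 (267 ± 21.4 against 163 ± 22.3 FPKM, adjusted p = 0.11), Ahctf1, the glucocorticoid-responsive Fkbp5 (3.82 ± 0.563 against 2.31 ± 0.156 FPKM), the glutathione transferase Gstp1 (225 ± 70.5 against 114 ± 14.9 FPKM), the glycine transporter Slc6a9, Tspan33 and the growth factor receptor Egfr (7.64 ± 2.38 against 2.89 ± 1.10 FPKM). Their log2 fold changes ran from −0.55 for Tspan33 to −1.34 for Egfr, with adjusted p-values up to 0.22 for Egfr. Cyp2b13, Ugt2b5, Gstp1, Klk1b4 and Slc22a29 have close paralogs, which makes their levels uncertain.

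Lists that bear on the title's pathway did not stand apart from other genes in RNA level. Only RNA was measured, so protein levels, phosphorylation and enzyme activity in that pathway were not tested. Of 34 fatty acid and triglyceride synthesis genes, 18 had positive and 16 negative log2 fold changes, with a median of 0.05 (camera adjusted p = 0.45), and 0 passed over all genes or adjusted over the list alone. Its members with the smallest p-values were Fads2 (239 ± 31.8 against 308 ± 57.7 FPKM), Pparg (3.83 ± 0.880 against 5.33 ± 1.42 FPKM) and Acaca (7.17 ± 1.39 against 5.46 ± 0.579 FPKM). The 27 insulin and PI3K-AKT genes had a median of 0.04 (adjusted p = 0.45), and 0 passed either way. Among them Insr read 4.71 ± 2.42 against 1.36 ± 1.52 FPKM (edgeR adjusted p = 0.40), Pik3cd 0.772 ± 0.0911 against 0.981 ± 0.208 FPKM, and Grb10 0.768 ± 0.152 against 0.557 ± 0.166 FPKM. The 15 inositol phosphatases had a median of 0.03 (adjusted p = 0.84) and the 12 members of the non-canonical NF-kB pathway a median of −0.04 (adjusted p = 0.37), with 0 passing in each, over all genes or adjusted over the list alone. Inppl1 (7.61 ± 1.45 against 5.65 ± 0.453 FPKM), Inpp5e and Mtmr2 led the former, and Traf2 and Ltb, beside Map3k14, the latter. Lipid droplet and fatty acid uptake genes (26 tested, adjusted p = 0.32; Vldlr, Plin5 and Lpl had the smallest p-values), fatty acid oxidation genes (40 tested, adjusted p = 0.30; Acot1, Hadh and Fgf21) and cholesterol synthesis genes (25 tested, adjusted p = 0.27) did not pass. Adjusted over the list alone, Acot1 was lower (10.6 ± 3.02 against 5.00 ± 1.56 FPKM), and no lipid droplet or cholesterol synthesis gene passed.

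Of 38 lists, 14 passed with camera's preset correlation, 8 higher and 6 lower in NIKhKO, and 0 passed with an estimated correlation. With fry, 0 of the 14 passed the test of movement on balance in one direction (lowest adjusted p = 0.15), while 8 passed its test of change in either direction, which compares a list with no other genes. The 8 were cytochrome P450 (adjusted p = 0.00019), inflammatory, male-biased, ethanol metabolism, cholangiocyte, female-biased, B and plasma cell, and ER stress genes (adjusted p = 0.041). Of the 24 lists that camera did not call, 6 passed that test too, the acute phase, pericentral, bile acid, inositol phosphatase (adjusted p = 0.014), lipoprotein assembly and circadian clock lists. All 7 tested B and plasma cell markers had positive log2 fold changes, with a median of 0.94 (camera adjusted p = 3.5e-07; adjusted p = 0.20 with an estimated correlation). Adjusted over the list alone, 5 were higher, Cd79a, Cd79b, Ighm, Ighd and Iglc2, and 0 passed over all genes. Ighd, which encodes the heavy chain of IgD, read 0.560 ± 0.233 against 1.66 ± 0.739 FPKM, Cd79a 0.785 ± 0.380 against 2.12 ± 0.807 FPKM and Iglc2 0.637 ± 0.434 against 1.67 ± 0.361 FPKM, all at low levels, and immunoglobulin genes share reads. In NIKhKO 4 this list's score was −0.39, among the NIKflox libraries, while the other NIKhKO libraries lay between 0.62 and 1.0 (mean of the centred log2 values). Of 33 interferon-stimulated genes 25 had positive log2 fold changes, with a median of 0.21 (adjusted p = 5.1e-05; adjusted p = 0.50 with an estimated correlation), and 3 were higher adjusted over the list alone, Usp18 (2.78 ± 0.435 against 5.07 ± 1.36 FPKM), Ifih1 and Gbp2. Antigen presentation genes had a median of 0.35, with 14 of 15 positive (adjusted p = 5.3e-05; adjusted p = 0.50 with an estimated correlation) and 0 passing adjusted over the list alone. H2-Ab1, H2-Eb1 and Cd74, the class II genes with the smallest p-values, are among them, with Cd74 at 24.1 ± 3.02 against 32.3 ± 10.2 FPKM.

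Ethanol metabolism genes were higher as a list, with 13 of 15 positive and a median of 0.24 (camera adjusted p = 0.00015; adjusted p = 0.20 with an estimated correlation). Adjusted over the list alone 4 were higher, the aldehyde dehydrogenases Aldh1b1 (44.7 ± 11.3 against 67.7 ± 12.7 FPKM) and Aldh3a2 (70.2 ± 7.77 against 84.7 ± 10.4 FPKM), Acss3 (6.49 ± 0.649 against 8.05 ± 0.541 FPKM) and Cyp2e1, the ethanol-inducible cytochrome P450. The alcohol dehydrogenase Adh1 (976 ± 35.5 against 948 ± 101 FPKM) did not move with the list, at a log2 fold change of 0.02. Neither did the aldehyde dehydrogenase Aldh2 (478 ± 18.9 against 464 ± 27.7 FPKM), also at 0.02. The 2 negative members were Adh4, at −0.16, and Sirt1, at −0.05. Of 30 oxidative phosphorylation genes 27 were positive, with a median of 0.13 (adjusted p = 0.00060; adjusted p = 0.64 with an estimated correlation) and 0 passing adjusted over the list alone; Sdhb read 78.0 ± 14.9 against 95.6 ± 2.63 FPKM, and Ndufb3 and Uqcrc1 followed. Cytochrome P450 and xenobiotic metabolism genes had a median of 0.11 (adjusted p = 0.018; adjusted p = 0.50 with an estimated correlation). Adjusted over the list alone, 4 were higher, Cyp2b9, Cyp2b10, Cyp2b13 and Cyp3a11, and 2 lower, Cyp2a4 (438 ± 96.4 against 202 ± 69.1 FPKM) and Ugt2b5. Inflammatory cytokines and NF-kB targets had a median of 0.18 (adjusted p = 0.030; adjusted p = 0.50 with an estimated correlation), with 0 passing adjusted over the list alone; Ccl5 (1.12 ± 0.342 against 2.01 ± 0.235 FPKM) and Cxcl1 had positive and Il1a negative log2 fold changes. Female-biased liver genes went both ways, 11 positive and 9 negative with a median of 0.09 (adjusted p = 0.033; adjusted p = 0.50 with an estimated correlation). Adjusted over the list alone 6 were higher and 4 lower, with Prom1 (1.09 ± 0.198 against 2.37 ± 0.809 FPKM) and Sult2a2 among those with the smallest p-values. The 4 lower, against the direction camera gave the list, were Cyp2a4, Cyp3a44 (36.2 ± 30.8 against 6.11 ± 2.38 FPKM), Cux2 and Sult3a1, the latter with the largest change of the list (log2 fold change −2.80).

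Extracellular matrix genes were lower as a list, with 26 of 26 negative and a median log2 fold change of −0.35 (camera adjusted p = 5.3e-05; adjusted p = 0.50 with an estimated correlation). No member passed, over all genes or adjusted over the list alone. Spp1 read 31.6 ± 9.24 against 19.2 ± 3.36 FPKM. Acta2 read 4.02 ± 5.96 against 0.874 ± 0.0857 FPKM and Tagln 4.88 ± 3.34 against 2.22 ± 0.504 FPKM, with NIKflox 2 at 14.6 and 10.4 FPKM. ER stress genes were also lower, with 22 of 25 negative and a median of −0.34 (adjusted p = 0.00019; adjusted p = 0.50 with an estimated correlation). Adjusted over the list alone 4 were lower, Sdf2l1, Creld2, Dnajc3 (34.4 ± 6.31 against 23.9 ± 2.19 FPKM) and Atf5 (423 ± 76.0 against 308 ± 22.2 FPKM), and 1 higher, Vldlr, which encodes a lipoprotein receptor. Transcripts of cardiac muscle were present in NIKflox 2 and 4, where a list of heart genes chosen after seeing the data summed to 16.9 and 52.2 FPKM against 1.71 to 4.85 FPKM in the other 8 libraries. NIKflox 2, with the highest extracellular matrix score (1.18), also had the highest scores of adipose tissue markers (1.42) and of monocyte and recruited macrophage markers (0.63), and NIKhKO 5, with the highest matrix score of the NIKhKO libraries (0.003), had the next highest adipose score (0.59). Without NIKflox 2 and 4 the median of the ER stress list was −0.13 (adjusted p = 0.17) and that of the extracellular matrix list −0.16 (adjusted p = 0.023).

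Stellate cell markers had a median of −0.16, with 17 of 17 negative (camera adjusted p = 0.0074; adjusted p = 0.50 with an estimated correlation), and Des, Vipr1 and Rgs5 had the smallest p-values. Sinusoidal endothelial markers had a median of −0.13, with 18 of 21 negative (adjusted p = 0.017; adjusted p = 0.64 with an estimated correlation), led by Flt1, Wnt2 and Pecam1. The scores of this list overlapped, with NIKhKO 3 and 4 at 0.22 and 0.21, above the NIKflox libraries other than NIKflox 2 (0.29), and NIKhKO 2 and 5 lowest at −0.25 and −0.55. Neither list had a member passing adjusted over the list alone. Male-biased liver genes had a median of −0.47, with 10 of 14 negative (adjusted p = 0.039; adjusted p = 0.50 with an estimated correlation), and 3 were lower adjusted over the list alone, Mup1, Gstp1 and Ugt2b38. Mup1, a major urinary protein gene with near-identical copies, read 1.78 ± 1.25 against 0.430 ± 0.264 FPKM. Cholangiocyte markers had a median of −0.53, with 9 of 11 negative (adjusted p = 0.039; adjusted p = 0.50 with an estimated correlation), and 2 were lower adjusted over the list alone, Krt19 (1.05 ± 0.0716 against 0.459 ± 0.211 FPKM) and Spp1. Onecut1 read 3.35 ± 0.789 against 1.64 ± 0.837 FPKM.

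Of the 14 called lists, 7 kept their call without any single library and 7 lost it without at least 1. Cholangiocyte markers lost it without NIKflox 2, 3 or 5 or NIKhKO 1, 2, 3 or 5 (camera adjusted p up to 0.12), and male-biased genes without NIKflox 1, 2 or 5 or NIKhKO 1, 2 or 5 (up to 0.14). Cytochrome P450 genes lost it without NIKflox 2 or 4 or NIKhKO 3 or 4 (up to 0.11), inflammatory genes without NIKflox 3 or 4 or NIKhKO 2 or 3 (up to 0.22), and female-biased genes without NIKflox 3 or 4 or NIKhKO 3 or 5 (up to 0.28). Sinusoidal endothelial markers lost it without NIKflox 2 or NIKhKO 2 or 5 (up to 0.33), and oxidative phosphorylation genes without NIKhKO 1 (0.0504).

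**Figure D2:**
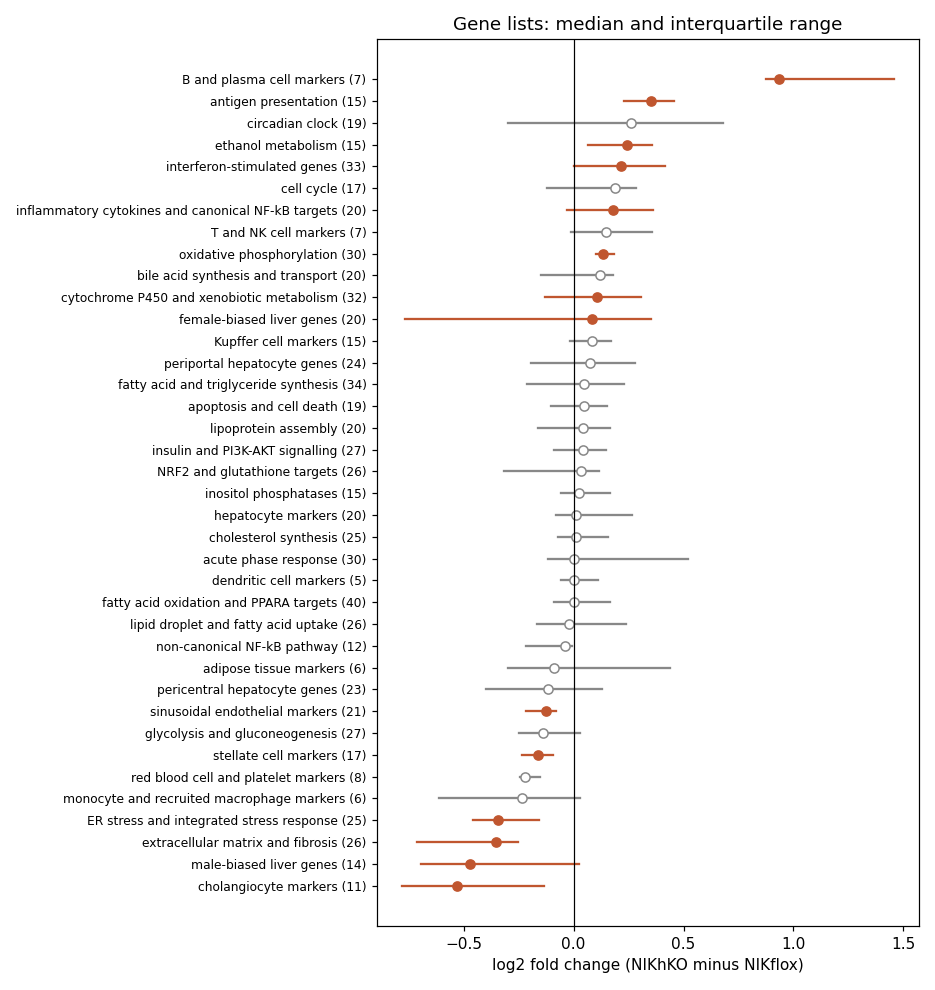
Median (points) and interquartile range (lines) of the log2 fold change, NIKhKO minus NIKflox, of the tested members of 38 gene lists, with the number of genes tested in brackets; filled points are the 14 lists that passed camera with its preset correlation. B and plasma cell markers lie highest at 0.94, and cholangiocyte markers lowest at −0.53.

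The remaining lists did not pass camera. Pericentral hepatocyte genes had a median of −0.12 (adjusted p = 0.26) and held Csad, the only list member called over all genes; adjusted over the list alone, Axin2, Tbx3 and Csad were lower and Cyp2e1 higher. Periportal genes had a median of 0.08 (adjusted p = 0.086), with Uroc1 (143 ± 20.3 against 189 ± 20.3 FPKM), Gls2 and Aldh1b1 higher adjusted over the list alone. The circadian clock list had a median of 0.26 (adjusted p = 0.099), with Nr1d1 (10.3 ± 3.64 against 20.3 ± 4.24 FPKM) and Dbp (1.38 ± 1.33 against 5.81 ± 3.72 FPKM) higher adjusted over the list alone. Acute phase genes had a median of 0.00 and divided evenly (adjusted p = 0.32), and 5 were higher and 2 lower adjusted over the list alone, with Orm3 (3.40 ± 2.06 against 11.9 ± 3.58 FPKM), Saa2 (1.75 ± 0.777 against 7.96 ± 3.88 FPKM) and Saa4 having the smallest p-values; the Saa and Orm genes share reads within their families. Akr1d1 of bile acid synthesis was higher adjusted over the list alone (67.1 ± 9.50 against 95.5 ± 9.60 FPKM; list adjusted p = 0.22), and Nr1h4 and Slco1a4 followed. Glycolysis and gluconeogenesis genes had a median of −0.14 (adjusted p = 0.081), with Pfkfb1 and Slc37a4 among those with the smallest p-values and 0 passing adjusted over the list alone.

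Camera adjusted p-values were 0.11 for T and NK cell markers, 0.22 for cell cycle genes, 0.23 for monocyte and recruited macrophage markers, 0.30 for hepatocyte markers, 0.32 for adipose tissue markers and 0.35 for red blood cell and platelet markers. They were 0.60 for Kupffer cell markers, 0.67 for apoptosis genes, 0.74 for lipoprotein assembly, 0.86 for dendritic cell markers and 0.90 for NRF2 and glutathione targets. For adipose tissue markers, lipid droplet genes and lipoprotein assembly the sign of the median and the direction of the test differed. Adjusted over these lists alone, the genes that passed were Ccl5 and Car3 on the higher side and Cd9, Spp1 and Gstp1 on the lower side.

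Among 3045 annotation terms, 68 passed camera with the preset correlation, 41 higher and 27 lower, and 0 with an estimated correlation, where each adjusted p was 1.0 after rounding. The terms with the smallest p-values were the cytosolic large ribosomal subunit, lower as a set, with 48 of 54 log2 fold changes negative and a median of −0.17 (adjusted p = 1.0e-07), the KEGG ribosome, also lower as a set, with 95 of 130 negative (adjusted p = 3.4e-05), and valine, leucine and isoleucine degradation, positive in 32 of 46 genes with a median of 0.19 (adjusted p = 5.9e-05). Protein disulfide isomerase activity was negative in 15 of 16 genes with a median of −0.34 (adjusted p = 9.0e-05), and KEGG oxidative phosphorylation positive in 101 of 119 genes with a median of 0.11 (adjusted p = 0.00044). The median log2 fold change of all genes was −0.01 in edgeR. In limma it was −0.05 on log2(FPKM + 1) and −0.11 with FPKM rescaled to a common sum, so that medians of this size depend on the test and the scaling.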

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

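The test of library quality for NIKhKO 4 was chosen only after the result was seen, as were the count over 24 genes, the list of heart genes and the choice to leave out NIKflox 2 and 4. Within the 5 libraries of a genotype, 7 of 82 values tested stood apart from the rest by Dixon's criterion for 5 samples (0.71), and chance alone would single out about 1 in 20 such groups. Map3k14 stood high in NIKflox 4, at 0.899 FPKM against 0.483 to 0.585 FPKM in the other NIKflox libraries. Acly stood high in NIKhKO 3, at 79.6 FPKM against 44.0 to 51.0 FPKM. The share of ribosomal and small non-coding RNA stood high in NIKflox 1, at 1.05% of counts against 0.316 to 0.479%, while NIKhKO 3, 4 and 5 lay higher, at 1.64, 1.37 and 2.08%. The score of sinusoidal endothelial markers stood high in NIKflox 2, at 0.29 against 0.01 to 0.09, and NIKflox 2 also had the highest scores of adipose tissue markers (1.42) and cell cycle genes (0.88).

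NIKhKO 4 stood apart from its genotype in Csad, at 6.57 FPKM against 2.84 to 3.75 FPKM, and in the score of B and plasma cell markers, at −0.39 against 0.62 to 1.0, and on the 50 genes that best separated the other 9 libraries its median position was 0.38, on a scale from 0 for NIKflox to 1 for NIKhKO, against 0.73 to 0.98 for the other NIKhKO libraries and 0.14 to 0.49 for held-out NIKflox libraries. A higher share of ribosomal and small non-coding RNA is argued against, since the NIKhKO libraries with more of it stood at 0.735 or more, but other sides of library quality were not tested and stay open: NIKhKO 4 had the highest mitochondrial share (12.7%) and the fewest genes detected (19868) of the 10 libraries. A wrong label may account for it under the rule set beforehand. NIKhKO 4 lay beyond the NIKflox range in 60% of the 50 genes, no more than the 74% of held-out NIKflox 3. The rule uses only that highest library, and held-out NIKflox 1, 2, 4 and 5 lay at 46, 58, 38 and 36%, below NIKhKO 4. Held-out NIKflox libraries were also compared with fewer NIKflox libraries than NIKhKO 4 was, which makes lying beyond the range easier. By position no NIKflox library lay at the NIKhKO end as a swap partner would, the highest being NIKflox 3 at 0.49. By the share of genes beyond the range, however, held-out NIKflox 3 equalled held-out NIKhKO 3, at 74% each. Of the 24 genes called without it, NIKhKO 4 lay beyond the NIKflox range on the NIKhKO side in 15, among them Csad, Sult2a3, Rcan2 and Cyp2b13. It did not in 9, among them Saa1, Saa2 and Car3. Map3k14 in NIKhKO 4 does not separate the labels, because the 0.389 FPKM measured has a counting interval of 0.274 to 0.535 FPKM (95%, counts divided by 4) that holds the values of NIKflox 2 and 5. Incomplete loss of Map3k14 cannot be told apart either, because the interval also holds the 0.520 FPKM its position would need.

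The score of extracellular matrix genes stood high in NIKflox 2, at 1.18 against −0.24 to 0.16, and NIKflox 2 and 4 held heart muscle transcripts, with Actc1 at 2.90 and 10.4 FPKM. The matrix score of NIKflox 4, which held more heart transcripts, was 0.10, within the range of the NIKflox libraries without them, which goes against heart tissue for the matrix list, whereas the ER stress scores of NIKflox 2 and 4, 0.42 and 0.54, were the highest of all libraries, and those of NIKflox 1, 3 and 5, −0.20 to −0.04, lay within the range of the NIKhKO libraries, −0.23 to 0.09. Heart tissue in these libraries may still have contributed to both lists, since without these libraries the median of the ER stress list moved from −0.34 to −0.13, and that of the extracellular matrix list from −0.35 to −0.16 with an adjusted p of 0.023. These are 39.0% and 44.4% of the full medians, between the bounds set beforehand for and against heart tissue as the whole cause. Any other trait that NIKflox 2 and 4 share leaves with them, so the test does not single out heart tissue. Fgf21, for example, also stood highest in both, at 16.4 and 18.1 FPKM. For the ER stress list, heart tissue, another shared trait of these libraries and genotype therefore cannot be told apart. For the matrix list a single library's score leaves heart tissue open. A difference between the genotypes remains open as the biological explanation.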

How the results depend on the processing

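Estimated counts divided by 4, filterByExpr, RLE factors, voom, log2 CPM and pairs of libraries left out were chosen after seeing the data. The test fixed beforehand for a table without counts was limma on log2(FPKM + 1). Against 2 genes higher and 1 lower, limma gave 0 and 0 on log2(FPKM + 1), on log2(FPKM + 0.1), on 3 rescaled forms of FPKM and with array weights, with 1273 to 1602 genes at an unadjusted p below 0.05. A minimum mean FPKM of 2 gave 6 and 2, robust shrinkage 4 and 2, voom with sample weights 3 and 2, and DESeq2 126 and 81; fewer genes are tested under the first, and the cause of the others was not tested. Leaving out NIKflox 2 and 4 gave 1 and 0, the 1 being Zhx3, and leaving out NIKflox 1 and NIKhKO 4 gave 1 and 1. Leaving out single libraries gave 0 to 16 higher and 0 to 8 lower. The replicate numbers did not pair the libraries (correlations of deviations from −0.25 to 0.05), and the replicate block gave 1 higher and 1 lower, 14 lists and 52 terms. No filter, RLE factors, filterByExpr and counts divided by 4 called the same 3 genes. Map3k14 stayed negative and Acly positive under all settings without passing, with adjusted p-values of 0.13 to 0.59 and 0.65 to 0.99, and Inpp5b stayed negative. The 14 lists became 0 with an estimated correlation, 0 with fry's one-way test (8 pass its test of change either way) and 7 at a mean FPKM of 2, where 32 lists were tested. Other settings called 10 to 17 lists in all, not always the same ones. Leaving out NIKflox 2 and 4 called 14, of which 9 were shared with the main test, and array weights called 17, of which 13 were shared. The 68 terms became 0 with an estimated correlation, 44 with array weights, 162 with no filter and 27 without NIKflox 2 and 4; the cause was not tested. For other named genes 2222 alternatives kept direction and side of the threshold, 48 lost and 63 gained the call; for called lists 238 kept it and 68 lost it; no direction turned. Reads were not subsampled, so how far depth limits low genes such as Map3k14 was not tested.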

Other observations

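The prediction for each test here was written before its result was seen. Ribosomal protein genes and oxidative phosphorylation genes had median log2 fold changes of opposite sign. Of 97 ribosomal protein genes of the cytosolic subunits 84 had negative log2 fold changes, with a median of −0.18, and of 30 oxidative phosphorylation genes 27 had positive ones, with a median of 0.13. The oxidative phosphorylation scores of the genotypes overlapped. NIKhKO 1 was highest at 0.24, while NIKhKO 3 and 4, at −0.02 and −0.05, lay within the NIKflox range of −0.20 to 0.05. That list lost its camera call without NIKhKO 1 (adjusted p = 0.0504) and with an estimated correlation (adjusted p = 0.64). Gene length bias may separate such groups, and the difference between the medians, 0.312, was 0.313 after the trend on length was removed. Median lengths, derived from counts and FPKM in relative units, were close, at 1895 for ribosomal protein and 2325 for oxidative phosphorylation genes. Removing a smooth trend thus had little room to change the difference and decides little. With the share of ribosomal and small non-coding RNA as a covariate the difference was 0.330, which argues against that share as its cause. A change with the genotype is a hypothesis that these data leave open, found and tested on the same libraries.

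Insr, the insulin receptor gene, fell into separate levels that cut across the genotypes. It read 4.08, 6.32, 6.85 and 5.48 FPKM in NIKflox 1, 2, 3 and 5 and 4.08 FPKM in NIKhKO 1, and 0.80 FPKM in NIKflox 4 and 0.554 to 0.766 FPKM in the other NIKhKO libraries. Fgf21, a liver hormone induced by fasting and stress, read 16.4 and 18.1 FPKM in NIKflox 2 and 4, the libraries with heart transcripts, and 2.47 to 4.42 FPKM in the other 8. Insr was chosen for this description after its values were seen, as was Fgf21.

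Other splits of the 10 libraries into 5 and 5 were tried, 100 of the 126 possible with the real one. As many called genes as the real 3 came from 4 of 100 splits (highest other 11), and as many genes at an unadjusted p below 0.05 as the real 1273 from 4 of 100 (highest other 1835), which is under 0.05 of the splits drawn for both. With 26 splits not drawn and the real one among the 4, this argues against chance only narrowly. As many called lists as the real 14 came from 16 of 100 splits (highest other 18), and as many called terms as the real 68 from 12 of 100 (highest other 141), so chance is not excluded for the number of lists or terms. The split with 11 called genes kept 4 NIKflox libraries together and so differed from the genotypes by exchanging 1 library of each.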
